A study of Mus musculus with 6 samples.

How the data were processed

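RNA was measured from the ventral cochlear nucleus (VCN), the lateral superior olive (LSO) and the trapezoid body nucleus MNTB of male C57BL/6J mice. Per the labels, tissue was pulled with forceps from fresh brainstem slices of 200 µm, and 1 pool per nucleus was made from 6 animals at P3 and from 3 at P14. Per the labels' protocols, RNA was purified with a Qiagen RNeasy kit, treated with DNase, amplified from 20 ng with a Nugen Ovation Pico system and hybridised to Affymetrix Mouse 430 2.0 arrays. The deposited values are log2 expression values per probe set, which the authors made with RMA (background correction, quantile normalization and summary over probes), per the submitters' processing notes; the version is not given in the sources used here. The values ran from 1.84 to 14.37, and the array medians, at 6.27 to 6.31, were in the range that quantile normalization leaves. Scan dates and batches are not given in the sources used here, so no batch was tested. Whether the 3 nuclei of an age came from the same animals is not given either. As these are arrays, their number limits the precision.

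The 45101 probe sets include 64 control sets. Through the platform annotation 34945 named 1 gene, 932 several and 9160 none here. A RefSeq table matched 34741 of the probe sets that name 1 gene, and no symbol changed. No coordinates are printed, because no genome or build is given here. Each of 18193 genes was represented by its probe set of highest mean over the 6 arrays, leaving out names ending in _x_at where another existed. Genes whose mean lay at or above the 40th percentile of all probe sets (5.57 log2 units) were tested, which left 12958. The 2537 tested probe sets with no gene named here were counted apart, and 1115 of them (43.9%) passed for age.

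The comparisons, the lists, the rule for naming genes and all alternatives but 1 were fixed before the data were examined. Values were fitted with limma 3.58.1 in R 4.3.3, with age and nucleus as additive terms over all 6 arrays, moderated variances with an intensity trend, and two-sided tests adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The age contrast rests on 3 nuclei, and each contrast between nuclei rests on 2 ages. There were 2 residual degrees of freedom and 3.94 from the prior. Differences between single arrays are given as values. Where every array of the lower group lay at or below the highest unspiked control value (4.42), a named difference is given as a bound, with values floored at the 25th percentile (4.47). For age the 10 largest rises and falls are named among genes past the threshold with the same sign in 3 nuclei, for nuclei the 5 highest and 5 lowest with the same sign at both ages (filled with the largest untested values of at least 1 log2 unit at both ages), and for each list up to 4 members. All members of the BMP and TGF-beta list could be named. Other genes named are members of the fixed lists, chosen after their values were seen.

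The 25 gene lists covered myelin and oligodendrocyte precursors, astrocytes, microglia, endothelium, meninges and choroid plexus, red blood cells, Schwann cells, cell cycle, immature neurons, axon guidance, hindbrain transcription factors, granule lineage, cholinergic and motor neurons, potassium channels, sodium and HCN channels, glutamate receptors, glycine and GABA transmission, presynaptic release, calcium binding, perineuronal nets, neurofilaments, energy supply, immediate early genes and BMP and TGF-beta signalling. Of 484 entries 437 had a probe set and 386 were tested. The 22 lists with at least 5 tested members entered limma's camera test with a preset correlation of 0.01, adjusted over lists, and were repeated with an estimated correlation and with fry, which asks whether the members move 1 way and makes no comparison with other genes. Differences between single arrays were set against 10000 random lists matched on mean expression.

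The steps were tested on simulated data with 200 of 12958 genes changed. For age, 80% of changes of 1 log2 unit and 100% of 2 were recovered, with 10 false calls among 190. For MNTB minus LSO these were 64% and 97%, with 15 false among 176. For MNTB minus VCN they were 53% and 97%, with 8 among 158, and for VCN minus LSO 63% and 95%, with 5 among 163. Each contrast was simulated in 1 draw, so the percentages of the contrasts between nuclei cannot be ranked. In the data 21, 78 and 48 genes passed for these contrasts. With fewer genes passing the adjustment is stricter, so recovery in the data may have been lower than simulated. Camera recovered 20 of 20 lists shifted by 0.5 log2 units, with 1 false call among the unshifted of 200 lists. With an estimated correlation it recovered 0 of them. The simulated genes were drawn independently, whereas the correlation estimated in the data reached 0.615 for the myelin and 0.749 for the microglial list. False calls of camera for such correlated lists were therefore not gauged.

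The alternatives were no filter, a filter at the 60th percentile, a floor at the 25th percentile (4.47), all probe sets or the median of a gene's probe sets, arrays centred on their medians, repeated quantile normalization, no intensity trend, robust moderation, a minimum of 1 log2 unit, a threshold of 0.10, no block for nucleus or for age, both arrays of a nucleus left out, and each array left out in turn. Camera with no filter and an estimated correlation together was added after seeing the data. Leaving out 1 array leaves its nucleus with a single array at the other age, which is then assumed to vary like the others. For age that single array adds nothing to the contrast, so leaving out either array of a nucleus, or both, gives the same difference. For a gene said not to pass without 1 named array, that array gave the highest adjusted p, and others could end the call too.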

Results

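Gene expression was measured on 6 Affymetrix Mouse 430 2.0 arrays, 1 for each combination of 3 auditory brainstem nuclei and 2 postnatal ages. The nuclei were the ventral cochlear nucleus (VCN), which receives the auditory nerve, and its targets in the superior olivary complex, the lateral superior olive (LSO) and the nucleus of the trapezoid body on its medial side (MNTB). Each array held RNA pooled from 6 male C57BL/6J mice at postnatal day 3 (P3) or from 3 at postnatal day 14 (P14). No combination was repeated, so the spread behind every test below is how far the age change varied between the 3 nuclei. All contrasts of a gene share that 1 spread, moderated over genes, so a contrast of 2 nuclei also draws on the arrays of the third. The p-values measure repetition over nuclei or ages, not over animals. The 6 arrays had medians of 6.27 to 6.31 log2 units. Xist, the transcript of the inactive X chromosome, stayed at 3.34 to 3.41 and the Y-linked Eif2s3y at 9.58 to 10.05. The difference between the 3' and the 5' probe sets of Gapdh, a measure of RNA and amplification quality, was 1.21 to 1.41 log2 units at P3 and 1.06 to 1.11 at P14. This difference and the pool size both went with age. A technical difference shared by the 3 arrays of an age would repeat over nuclei and cannot be told apart from age. Age accounted for 68.8% of the variation between arrays over the tested genes, nucleus for 21.9% and the remainder for 9.31%. Precision is limited by the number of arrays.

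The first comparison asks which genes changed in all 3 nuclei between P3, before the onset of hearing, and P14, shortly after it. The largest rises were in genes of myelinating oligodendrocytes. Ermn, which encodes the oligodendrocyte cytoskeletal protein ermin, rose by 6.22 ± 0.60 log2 units (standard error, 3 nuclei, adjusted p = 0.00103), and the myelin membrane genes Mog and Mal rose by 5.68 and 5.40. Gsn, an actin-severing protein, followed at 4.82, with Ppp1r14a at 4.74, Fam107a at 4.69, the link protein gene Hapln2 at 4.65, the receptor gene Gpr62 at 4.34, the potassium channel subunit gene Kcng4 at 4.22 and the neuregulin receptor gene Erbb3 at 4.17. The largest fall was that of Cxadr, an adhesion molecule known as the coxsackievirus and adenovirus receptor, at -3.53 ± 0.13 (adjusted p = 0.000243). It was followed by the retinoic acid binding protein gene Crabp1 at -3.29, Rapgefl1 at -3.12, the kinase gene Pak6 at -3.0, Ablim3 at -2.88, the polysialyltransferase gene St8sia2 at -2.70, the RNA-binding protein gene Celf5 at -2.61, and Plppr1, Stum and Rasgrp2 at -2.52 to -2.45. All 20 changes had the same sign in 3 of 3 nuclei, which the rule for naming them required.

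Of 12958 genes tested with limma, 5317 passed, 3029 of them higher and 2288 lower at P14, and 5315 had the same sign in all 3 nuclei. The test itself favours such agreement, because its spread is how far the age change varied between nuclei. Over all tested genes 67.9% had the same sign in all 3 nuclei. A change of at least 1 log2 unit was found for 1363 of the 5317, 850 higher and 513 lower. Centring each array on its median turned the balance to 2432 higher and 3004 lower, so the balance of rises and falls depended on the scaling. The count was 3142 without the MNTB array of P3 and 3176 without that of P14. The second probe set of Gpr62 had a difference of -0.21, the 6 probe sets of Gsn ranged from -0.26 to 4.82, the 5 of Cxadr from -3.74 to -0.18, the 3 of Plppr1 from -2.51 to -1.25 and the 3 of Rasgrp2 from -2.45 to -0.78. With the median of a gene's probe sets Gpr62 was at 2.07, Hapln2 at 2.79 and Rasgrp2 at -1.42, all still past the test. In LSO and MNTB at P3 Hapln2 lay at 3.91 and 3.94, within the range of unspiked control sets (2.84 to 4.42), so that its rise there is a lower bound. Ermn lay within that range in MNTB at P3, so that its rise in MNTB is a lower bound too. Without nucleus in the model Pmp22, Drp2, Cbln3, Pax6, Slc5a7, Calcb, Slit3, Cacng5, Atoh7 and Tfap2b, named below, did not pass (adjusted p = 0.0517 to 0.846).

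Myelin genes rose as a group. All 16 tested members of the list of myelin and mature oligodendrocyte genes passed, with a median of 3.09, and all 16 also passed when adjusted over the list alone. Besides Ermn and Mog, the basic protein gene Mbp, already at a mean of 12.58 log2 units at P3, rose by 1.04, and the gap junction gene Gjb1, within the range of unspiked control sets at P3, rose by at least 3.59. The list stood apart from other genes in limma's camera test (adjusted p = 8.14e-10, but adjusted p = 0.563 with an estimated correlation). Of 9 genes of oligodendrocyte precursors, 4 rose and 2 fell, with the same counts adjusted over the list alone: Gpr17 rose by 1.28 and Sox10 by 1.04, whereas the growth factor receptor gene Pdgfra fell by 0.59 and Ptprz1 by 0.94 (list adjusted p = 0.573). Among 14 astrocyte genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.55. The connexin gene Gjb6 rose by 3.49 and the neurotensin receptor gene Ntsr2 by 2.55, while Aldh1l1 fell by 0.83 (-0.39 with the median of its probe sets) and the glutamate transporter gene Slc1a3 by 0.81. In fry the astrocyte list did not pass (adjusted p = 0.0653). The astrocyte list passed camera (adjusted p = 0.0371, adjusted p = 0.719 with an estimated correlation), but not without the LSO array of P3 (0.0715) or of P14 (0.0729).

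**Figure D1:**
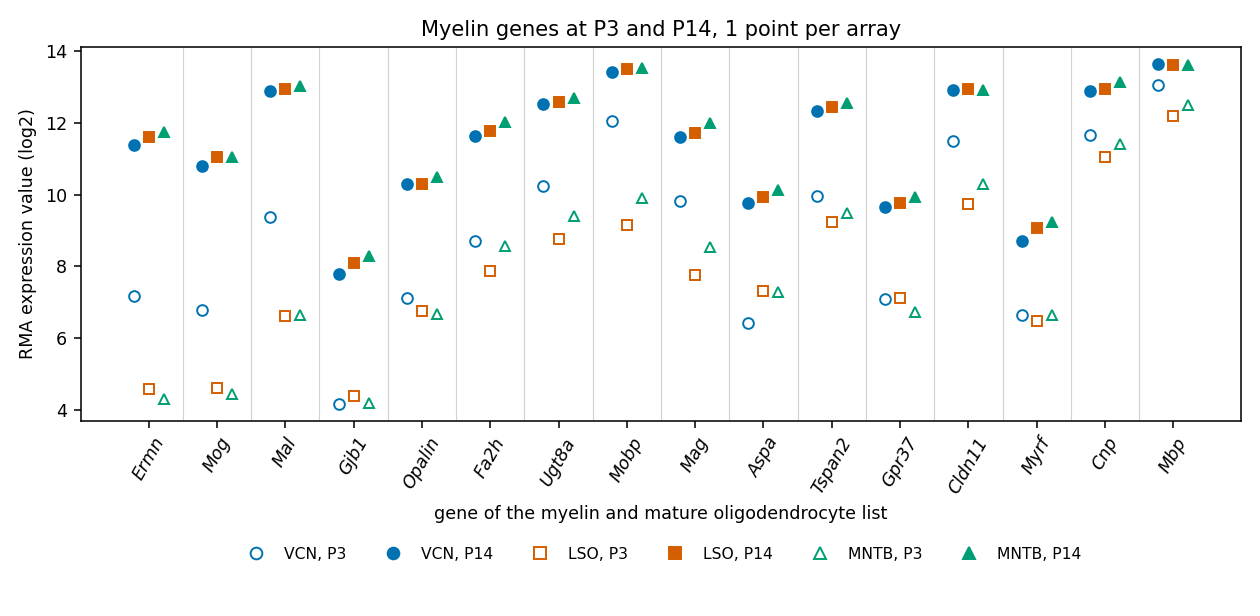
Log2 expression of myelin genes on each array, with P3 as open and P14 as filled markers, VCN as blue circles, LSO as orange squares and MNTB as green triangles. At P3 the VCN array lies above the other arrays for Mobp (12.06 against 9.15 and 9.92) and Mal (9.38 against 6.63 and 6.64), and at P14 the 3 nuclei lie close together.

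Vessel, meningeal, immune and blood cell genes were also higher at P14. Of 12 endothelial and pericyte genes, 10 rose and none fell (12 and 0 adjusted over the list alone), with a median of 0.84. The transporter gene Slco1a4 of the blood-brain barrier rose by 3.12 and the VEGF receptor gene Flt1 by 1.34 (list adjusted p = 7.79e-05, adjusted p = 0.684 with an estimated correlation). Of 7 genes of meninges and choroid plexus, 6 rose, both over all genes and adjusted over the list alone, led by the collagen genes Col3a1 at 3.16 and Col1a1 at 2.88. That list passed camera (adjusted p = 0.00148, adjusted p = 0.563 with an estimated correlation). Its member Ttr, the transthyretin gene of the choroid plexus, did not pass. Ttr stood at 12.58 on the VCN array of P14 and between 6.61 and 6.93 on the other 5. Microglial genes rose in 7 of 12 cases (8 adjusted over the list alone), with Tmem119 at 1.45 and the purinergic receptor gene P2ry12 at 0.78. Camera gave adjusted p = 0.00443 for them, and adjusted p = 0.703 with an estimated correlation. Fry did not call them (adjusted p = 0.104). Their median change was 1.08 in VCN, 0.71 in LSO and 0.10 in MNTB, at percentiles 99.99, 99.95 and 69.8 among random lists of matched expression, a difference that was not tested. Only 3 red blood cell genes were tested, too few for a list test, and all 3 rose: Hbb-b2 by 1.26 (0.82 with the median of its probe sets), Alas2 by 1.08 and Slc4a1 by 0.91. Of 3 tested Schwann cell genes, Pmp22 rose by 1.07 and Drp2 fell by 0.45, the second not without the MNTB array of P3 (adjusted p = 0.0847) or with the median of its probe sets (-0.26, 0.131).

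Genes of dividing cells and of growing neurons fell. Of 19 cell cycle genes, 18 fell and none rose, over all genes and adjusted over the list alone, with a median of -0.76. The ribonucleotide reductase gene Rrm2 fell by 1.40 and the replication helicase gene Mcm5 by 1.32 (list adjusted p = 4.57e-08, adjusted p = 0.563 with an estimated correlation). In the list of immature neuron and axon growth genes, 18 of 21 fell and none rose on either count, with a median of -1.06. The microtubule protein gene Dcx of migrating neurons fell by 2.42 and Draxin, a repulsive guidance protein, by 2.37 (list adjusted p = 8.14e-10, adjusted p = 0.563 with an estimated correlation). Transcription factors of hindbrain patterning fell in 12 of 21 cases and rose in 1 (13 and 1 adjusted over the list alone). Hoxd3 fell by 2.26 and Tfap2b by 2.20. The single riser was Atoh7 at 1.21, whose second probe set gave -0.04. It passed in 2 of the 6 fits with 1 array left out (highest adjusted p = 0.187, without the LSO array of P3). With the median of its probe sets it did not pass (0.0738). Camera placed this list lower (adjusted p = 0.000132, adjusted p = 0.563 with an estimated correlation). Axon guidance genes split, with 12 of 26 lower and 5 higher (14 and 5 adjusted over the list alone). The ephrin gene Efna3 fell by 2.05 and the Eph receptor gene Epha3 by 1.66, while Efnb3 rose by 1.41 and Slit3 by 0.92, the last not without the MNTB array of P3 (adjusted p = 0.0813). The guidance list was lower in camera (adjusted p = 0.0104, adjusted p = 0.563 with an estimated correlation).

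Among genes of synaptic transmission, some rose and others fell within every list. Ionotropic glutamate receptor genes and their partners fell in 9 of 19 cases and rose in 3 (11 and 3 adjusted over the list alone). The kainate receptor gene Grik1 fell by 1.71 and the NMDA receptor gene Grin2b by 1.57, whereas Grin2c rose by 1.98 and Cacng5 by 1.03. Cacng5 passed in 2 of the 6 fits with 1 array left out (highest adjusted p = 0.132, without the MNTB array of P14). Camera placed the list lower (adjusted p = 0.0104, adjusted p = 0.563 with an estimated correlation). Of 31 genes of the presynaptic release machinery, 14 fell and 6 rose (16 and 7 adjusted over the list alone). Doc2b fell by 2.15 and the syntaxin gene Stx1a by 1.97, while the synaptobrevin gene Vamp1 rose by 1.09 and Rims2 by 1.04, with probe sets of Rims2 from -0.44 to 1.37. This list also lay lower (adjusted p = 0.0222, adjusted p = 0.703 with an estimated correlation), but fry did not call it (adjusted p = 0.0703). In the list of glycine and GABA transmission, 6 of 21 rose and 6 fell, and the same numbers when adjusted over the list alone. The GABA receptor gene Gabrd rose by 2.38 (1.34 without either VCN array and 1.13 with the median of its probe sets), not without the LSO array of P3 (adjusted p = 0.0647), and the chloride importer gene Slc12a2 rose by 1.77. The subunit gene Glra2 of fetal glycine receptors fell by 2.06 and Gabrg3 by 1.44, and Glra1, of the adult glycine receptor, rose by 1.36 (list adjusted p = 0.820). Calcium binding proteins included the parvalbumin gene Pvalb, which rose by 3.44, and Necab2 and Hpca, which fell by 1.27 and 1.12. Of 12 such genes, 2 rose and 6 fell (3 and 6 adjusted over the list alone, list adjusted p = 0.277).

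Ion channel genes moved both ways. Of 23 potassium channel genes, 8 rose and 7 fell (8 and 8 adjusted over the list alone): the low-threshold channel gene Kcna1 rose by 2.37, Kcnk1 by 2.22 and the fast-spiking channel gene Kcnc1 by 1.35 (0.67 and adjusted p = 0.0569 with the median of its probe sets), while Kcnip1 fell by 1.05 and Kcnq3 by 0.93, the last not without the MNTB array of P3 (adjusted p = 0.0548). The list as a whole did not pass (adjusted p = 0.789). Of 12 sodium and HCN channel genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone). The beta subunit gene Scn4b rose by 3.18 and Scn2b by 1.62, whereas Scn3b fell by 2.12 and Scn3a by 2.11 (-1.39 with the median of its probe sets). The median of this list was 0.14, its mean -0.04, and camera pointed lower without passing (adjusted p = 0.929). Sodium pump and energy supply genes rose in 10 of 15 cases and fell in 2, on either count, with the cytochrome oxidase subunit gene Cox7a1 at 1.35 and the glycolytic gene Ldha at -0.69 (list adjusted p = 0.0274, adjusted p = 0.782 with an estimated correlation). The list was not called by fry (adjusted p = 0.128). That list did not pass without the VCN array of P3 (0.0549) or of P14 (0.0552).

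Matrix, axonal and activity genes gave the following counts. In perineuronal net matrix, 4 of 11 genes rose and 3 fell (5 and 3 adjusted over the list alone): Hapln4 rose by 2.45 and Tnc, the tenascin C gene, fell by 2.19, beside Hapln2 and Ptprz1 above. Its median of 0.03 became -0.07 with centring and -0.02 with quantile normalization (list adjusted p = 0.820). Of 15 neurofilament and axonal cytoskeleton genes, 6 rose and 4 fell, on either count, with the node protein gene Nfasc at 1.74, the heavy neurofilament gene Nefh at 1.41, the tau gene Mapt at -1.42 and Map2 at -0.62, the last at -1.04 with the median of its probe sets (list adjusted p = 0.698). Of 11 immediate early genes, Arc rose by 1.49 and Dusp1 by 0.54. Dusp1 passed in 2 of the 6 fits with 1 array left out (highest adjusted p = 0.170, without the MNTB array of P14). When adjusted over the list alone 1 passed (list adjusted p = 0.361). Of 9 tested genes in the list named for cerebellum and the rhombic lip granule lineage, Cbln3 rose by 2.00, Pcp2 by 0.89 and Pax6 fell by 0.99. The counts were the same adjusted over the list alone (list adjusted p = 0.844). Membership of the list does not make each gene one of granule cells. With the median of a gene's probe sets Pax6 was at -0.65 and Pcp2 at 0.01 (adjusted p = 0.977). Among 4 tested cholinergic and motor neuron genes, the choline transporter gene Slc5a7 rose by 0.54 and the CGRP gene Calcb had a value of -0.52. Each passed in 2 of the 6 fits with 1 array left out (highest adjusted p = 0.189 and 0.130, without the MNTB array of P14). Calcb lay within the range of unspiked control sets in VCN and MNTB at both ages, and with values floored at the 25th percentile it was at -0.19 (0.387).

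Genes of BMP and TGF-beta signalling, the pathway this series is known for, went both ways with age. Of 40 tested members, 8 rose and 11 fell (9 and 12 adjusted over the list alone). The list is known from the study of these samples and is not independent evidence. Smad7, an inhibitor of the pathway, rose by 2.59, and the ligand genes Bmp5, Bmp4, Inhbb and Bmp6 rose by 1.86, 1.69, 1.65 and 1.0. Among receptors, Acvrl1 rose by 0.81 and Tgfbr2 by 0.80, while Acvr2a fell by 1.37, Acvr2b by 0.60 and Bmpr1a by 0.37. The signal transducer genes Smad1, Smad5 and Smad2 fell by 0.44, 0.41 and 0.40, and the antagonist gene Grem1 fell by 0.93. Bambi rose by 0.83, and Acvr1b, Tgfb2, Bmp7 and Id4 fell by 0.59, 0.58, 0.50 and 0.27. Of the 6 fits with 1 array left out, Inhbb, Acvr1b, Acvr2b, Smad5, Tgfb2, Bmp7 and Smad2 passed in 2. Bambi, Bmpr1a, Id4 and Grem1 passed in 4. The highest adjusted p came without the MNTB array of P3 for Inhbb (0.119), Acvr1b (0.0827), Acvr2b (0.136), Smad5 (0.113), Tgfb2 (0.0708), Bambi (0.0791), Bmpr1a (0.0835) and Id4 (0.108). It came without that of P14 for Bmp7 (0.146) and Grem1 (0.0661), and without the LSO array of P3 for Smad2 (0.191). For age, leaving out the other array of the same nucleus gave the same difference. With the median of a gene's probe sets Tgfbr2 did not pass, at 0.23 (adjusted p = 0.267), while Bmp5 at 0.72, Smad2 at -0.62 and Id4 at -1.01 did, and Bmp7 (0.0768), Acvr1b (0.0528) and Acvr2b (0.0635) did not pass. Without nucleus in the model Bmp5 (0.118), Bmp6 (0.143), Bmp7 (0.0864), Tgfb2 (0.0956) and Bambi (0.0632) did not pass, their values being the same. The median of the list was 0.08, turning to -0.01 with centring, its mean was 0.21, and camera pointed lower without passing (adjusted p = 0.820).

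Within single nuclei, where each change is 1 array against 1 and has no test, the median rise of the myelin list was 2.47 in VCN, 3.63 in LSO and 3.36 in MNTB, each at percentile 100 among 10000 random lists of matched expression. The smaller value in VCN went with higher levels at P3: Ermn stood at 7.19 in VCN at that age, against 4.58 in LSO and 4.31 in MNTB, and Mog at 6.80 against 4.62 and 4.45. At P3 the myelin median of VCN minus LSO was 0.86, and at P14 it was -0.10. Median changes of all 3 nuclei had 1 sign in 16 of the 22 lists, and in 15 with arrays centred on their medians.

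**Figure D2:**
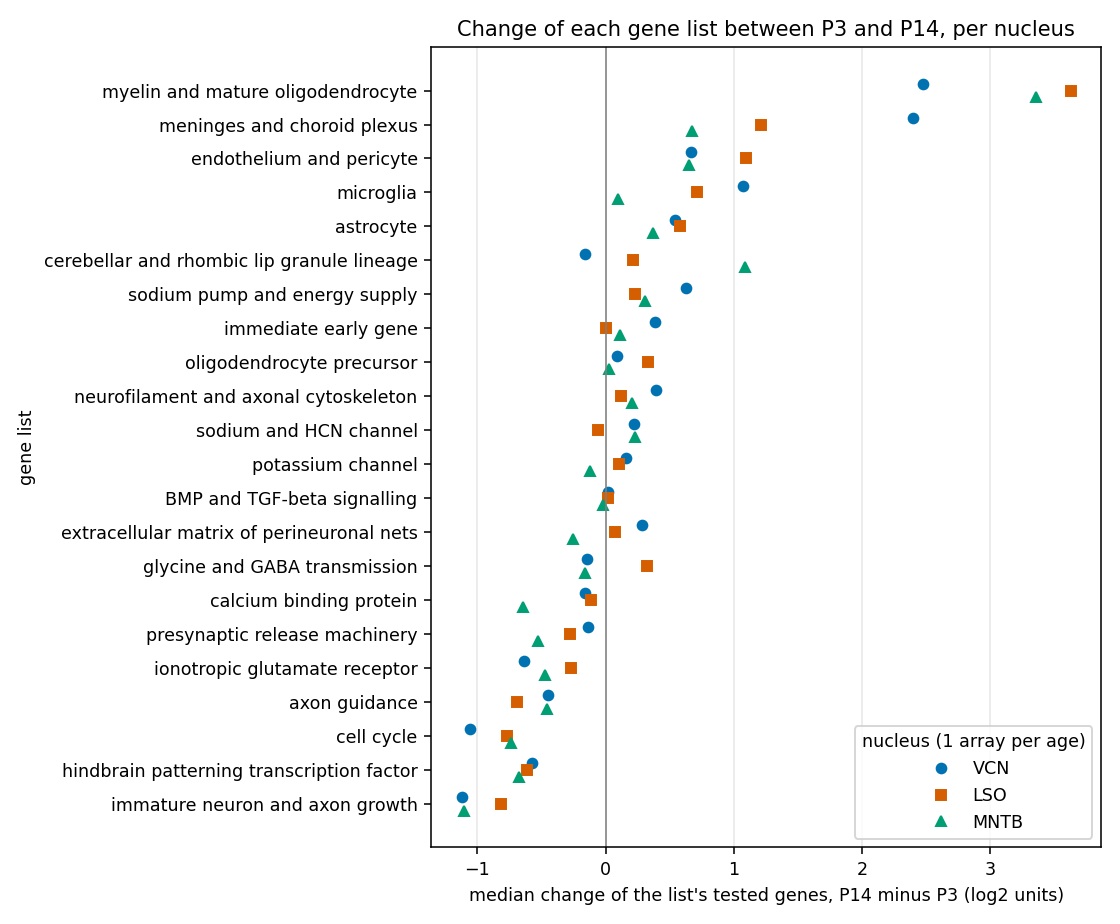
Median change from P3 to P14 (log2) over the tested genes of each gene list, with 1 marker per nucleus (VCN as blue circles, LSO as orange squares, MNTB as green triangles), each from 1 array per age. Myelin genes lie farthest to the right, at 2.47 to 3.63, and the immature neuron list lies lowest.

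The second comparison asks what sets the inhibitory relay nucleus MNTB apart from LSO at both ages. The 4 tested of 8 measured genes of the cholinergic and motor neuron list were lower in MNTB, and Slc18a3 and Calcb reached the filter through their levels in LSO. The list entered camera only with no filter, where it lay lower (adjusted p = 4.76e-11, but adjusted p = 0.424 with an estimated correlation). Of the 4 below the filter, Isl1 stood at 7.10 in LSO and 4.17 in MNTB at P14, Ucn stood at 5.10 to 5.43 on all 6 arrays, and Chat and Mnx1 were not above the unspiked control sets on any array, so that no difference could be seen. The noradrenaline transporter gene Slc6a2 differed by -5.87 ± 0.25 log2 units (standard error, 2 ages, adjusted p = 0.00159), at -5.36 at P3 and -6.38 at P14. The T-box factor gene Tbx20 of cranial motor neurons differed by -5.39, the vesicular acetylcholine transporter gene Slc18a3 by -4.53, the intermediate filament gene Prph by -4.40 (adjusted p = 0.0395) and the choline transporter gene Slc5a7 by -3.21 (adjusted p = 0.00644). The difference of the CGRP gene Calcb, within the range of unspiked control sets in MNTB, had a bound of -4.59. The guidance gene Sema3c at -2.21, the paired box gene Pax3 at -1.88 and Glra2 at -1.79 also passed. No gene passed as higher in MNTB, although 18 did without either VCN array and 1 with the median of a gene's probe sets. Among genes at least 1 log2 unit higher in MNTB at both ages, the largest values were those of the orphan receptor gene Esrrb at 2.19 (adjusted p = 0.558), the link protein gene Hapln1 at 2.12 (0.428), Bmp5 at 1.69 (0.104), the homeobox gene Otp at 1.60 and the potassium channel subunit gene Kcnmb2 at 1.56.

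In all, 21 genes passed with limma, 0 higher and 21 lower, against 881 at an unadjusted p under 0.05. All 21 differed by at least 1 log2 unit. Slc6a2, Calcb and Slc18a3 passed with every array left out in turn. Without the LSO array of P3 or of P14 4 genes passed in each case, without the MNTB array of P3 10 and of P14 6, and without the VCN arrays of P3 and P14 98 and 99, with 18 of them higher in each case. Tbx20 and Slc5a7 lost their calls when either LSO array was left out, at -5.62 to -5.17 and -3.46 to -2.97. Prph, Sema3c, Pax3 and Glra2 lost theirs when any 1 of the LSO or MNTB arrays was left out. Their differences then ranged from -4.97 to -3.82, -2.49 to -1.94, -2.03 to -1.73 and -2.05 to -1.53. Each such fit leaves 1 array for that nucleus. The 3 probe sets of Prph ranged from -4.40 to -0.21 and those of Slc6a2 from -5.87 to -2.40. The 2 of Otp were at 0.18 and 1.60, and the 2 of Bmp5 at 0.72 and 1.69. With the median of a gene's probe sets Prph was at -0.72 (adjusted p = 0.599) and Pax3 at -1.50 (0.152).

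Among the lists, 7 passed camera between MNTB and LSO, and none of the 7 did with an estimated correlation. Axon guidance genes lay lower in MNTB, with a median of -0.32, Sema3c as the 1 member past the test and 2 when adjusted over the list alone (adjusted p = 0.000211, adjusted p = 0.497 with an estimated correlation). Perineuronal net genes lay higher, with a median of 0.16, none past the test and 2 adjusted over the list alone, and values of 2.12 for Hapln1 and 0.84 for the aggrecan gene Acan (adjusted p = 0.00182, adjusted p = 0.497 with an estimated correlation). Cell cycle genes lay 0.21 higher (adjusted p = 8.37e-05) and oligodendrocyte precursor genes 0.22 higher (0.000211), both with adjusted p = 0.671 with an estimated correlation. The precursor list did not pass without the LSO array of P3 (0.132). Neurofilament genes had a median of -0.25 (adjusted p = 0.00286, adjusted p = 0.497 with an estimated correlation), with 4 lower when adjusted over the list alone. They did not pass without the LSO array of P3 (0.0697) or the MNTB array of P3 (0.0799). Glutamate receptor genes had a median of -0.20 (adjusted p = 0.00519, adjusted p = 0.503 with an estimated correlation), lost without the LSO or the MNTB array of P14 (0.477 and 0.0857). Myelin genes had a median of 0.17 (adjusted p = 0.0363, adjusted p = 0.671 with an estimated correlation), lost with centring (0.113) and with no filter (0.111), and turned to the other side without the LSO array of P3 (0.844) or the MNTB array of P14 (0.889).

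BMP and TGF-beta genes, again not independent evidence, had a median of -0.01 between MNTB and LSO, which became 0.06 with centring and 0.00 with quantile normalization, and a mean of 0.04. None of the 40 passed over all genes, and 1, Bmp5, passed adjusted over the list alone (camera adjusted p = 0.514). Bmp5 stood at 7.97 in MNTB, 6.03 in LSO and 5.61 in VCN at P3, and at 9.80, 8.35 and 7.03 at P14.

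At single ages the differences between MNTB and LSO are 1 array against 1 and carry no test. Among tested genes, the highest values for MNTB at P3 were Hapln1 at 3.01, Endou at 2.50, Esrrb at 2.09, Bmp5 at 1.94 and Tmem182 at 1.86. At P14 they were the calbindin gene Calb1 at 3.35, Esrrb at 2.29, the carbonic anhydrase gene Car12 at 2.24, the inhibin and activin subunit gene Inhbb at 2.09 and Kcnmb2 at 1.94. The 5 lowest tested genes were Slc6a2, Tbx20, Calcb, Slc18a3 and Prph at both ages.

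The third comparison sets MNTB against VCN, the source of its excitatory input. The list of cerebellar and rhombic lip granule genes lay lower in MNTB (adjusted p = 2.51e-09, but adjusted p = 0.474 with an estimated correlation). The corticotropin releasing hormone binding protein gene Crhbp was higher by 4.16 ± 0.18 log2 units (standard error, 2 ages, adjusted p = 0.00324), the transcription factor genes Tal1 by 3.03 and Gata3, within the range of unspiked control sets in VCN, by at least 2.86, Bmp5 by 2.57 (adjusted p = 0.0183) and the serotonin transporter gene Slc6a4 by 2.50. The zinc finger genes Zic1 and Zic5 both differed by -5.41, the neuronal basic helix-loop-helix genes Neurod2 by -4.81 (adjusted p = 0.000826) and Neurod1 by -4.46, and Bnc2 by -4.72. The glycine transporter gene Slc6a5, at 1.94, and the vesicular inhibitory transmitter transporter gene Slc32a1, at 1.72, were higher in MNTB, and the vesicular glutamate transporter gene Slc17a6 was lower, at -2.66. The glycine and GABA list as a whole did not pass, with a median of 0.06 and 2 of 21 genes higher and 1 lower (3 and 1 adjusted over the list alone, list adjusted p = 0.673). Further genes past the test were Sv2c at 1.31, Lhx5 at 1.47, Atoh7 at -3.98, Lhx2 at -3.35, Nrn1 at -3.29, Glra2 at -1.66 and Efna5 at -1.19.

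In all, 78 genes passed with limma, 21 higher and 57 lower in MNTB. The count was 215 and 148 without the VCN arrays of P3 and P14, 19 without either LSO array (4 higher), and 17 and 19 without the MNTB arrays of P3 and P14 (1 and 4 higher). Crhbp, Bnc2, Neurod1, Neurod2 and Cbln1 passed with every array left out in turn. For the others the highest adjusted p with 1 array left out was reached without the MNTB array of P3, at 0.0728 for Gata3, 0.248 for Tal1, 0.184 for Slc6a4, 0.0923 for Zic1, 0.106 for Zic5, 0.0736 for Slc32a1, 0.0888 for Lhx2, 0.185 for Lhx5 and 0.180 for Sv2c. It was reached without the MNTB array of P14 at 0.127 for Bmp5, 0.227 for Slc6a5, 0.160 for Glra2 and 0.317 for Efna5, and without the LSO array of P3 at 0.0766 for Atoh7, 0.106 for Nrn1 and 0.0841 for Slc17a6. The 2 probe sets of Atoh7 ranged from -3.98 to -0.05, those of Zic5 from -5.41 to -1.95, of Neurod2 from -4.81 to -2.35 and of Bmp5 from 1.19 to 2.57. With the median of a gene's probe sets Bmp5 (adjusted p = 0.133) and Efna5 (0.0818) did not pass, and Atoh7 and Neurod2 were at -2.02 and -2.33.

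The granule lineage list had the largest shift between MNTB and VCN, with a median of -1.82, but fry did not call it (adjusted p = 0.0806). Of its 9 tested genes 4 were lower (1 higher and 6 lower adjusted over the list alone), including Zic1, Neurod1 and the cerebellin gene Cbln1 at -3.73. Another 6 lists passed camera, each with adjusted p = 0.528 with an estimated correlation. Oligodendrocyte precursor genes had a median of 0.42 (adjusted p = 7.66e-05), with none past the test but 5 adjusted over the list alone, and a value of 0.64 for Sox10. Cell cycle genes had a median of 0.26 (0.000700), lost without the VCN array of P14 (0.403) or the MNTB array of P14 (0.0542). Perineuronal net genes had a median of 0.19 (0.00919), lost without the VCN array of P14 (0.0826). The immature neuron list, with Nrn1 its 1 member past the test and 2 adjusted over the list alone, had a median of -0.11 (0.00494), lost without the VCN array of P3 (0.860). Meningeal and choroid plexus genes had a median of -0.37 (0.00902), lost without the VCN array of P14 (0.403) or the MNTB array of P14 (0.656). In that list Ttr differed by -5.65 at P14. Neurofilament genes had a median of -0.07 (0.0207), lost without the MNTB array of P3 (0.291) or the VCN array of P14 (0.107). Of the 40 BMP and TGF-beta genes, not independent evidence, Bmp5 passed, and adjusted over the list alone 1 was higher and 2 were lower (list adjusted p = 0.207). With no filter the cholinergic and motor neuron list lay higher in MNTB than in VCN in camera (adjusted p = 0.0270, but adjusted p = 0.596 with an estimated correlation). The largest difference was that of Prph, at 7.69 in MNTB and 4.65 in VCN at P3, and at 6.24 and 5.06 at P14. Its 3 probe sets ranged from 0.15 to 2.11. Isl1, Calcb, Chat and Mnx1 were not above the unspiked control sets in either nucleus.

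The fourth comparison sets VCN against LSO. The list of cerebellar and rhombic lip granule genes lay higher in VCN (adjusted p = 1.90e-12, but adjusted p = 0.356 with an estimated correlation), and the 4 tested of 8 measured cholinergic and motor neuron genes were lower. With no filter that list lay lower in camera (adjusted p = 2.61e-12, but adjusted p = 0.214 with an estimated correlation). Zic1 was higher by 4.15 ± 0.47 log2 units (standard error, 2 ages, adjusted p = 0.0355), the dynein light chain gene Dynlrb2 of motile cilia by 4.07, Bnc2 by 3.96, Neurod1 by 3.48 and Fam216b by at least 3.34. Prph differed by -6.50, Slc6a2 by -5.67 and the motor neuron gene Chodl by -5.07, and the differences of Tbx20 (adjusted p = 0.00143) and Calcb had bounds of -5.58 and -4.59. Fam216b in LSO, and Tbx20 and Calcb in VCN, lay within the range of unspiked control sets. Dynlrb2 lay within it in LSO at P3, at 4.05, so its difference at that age is a lower bound. Slc32a1, at -1.09, and Sema3c, at -2.09, were lower in VCN as well.

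**Figure D3:**
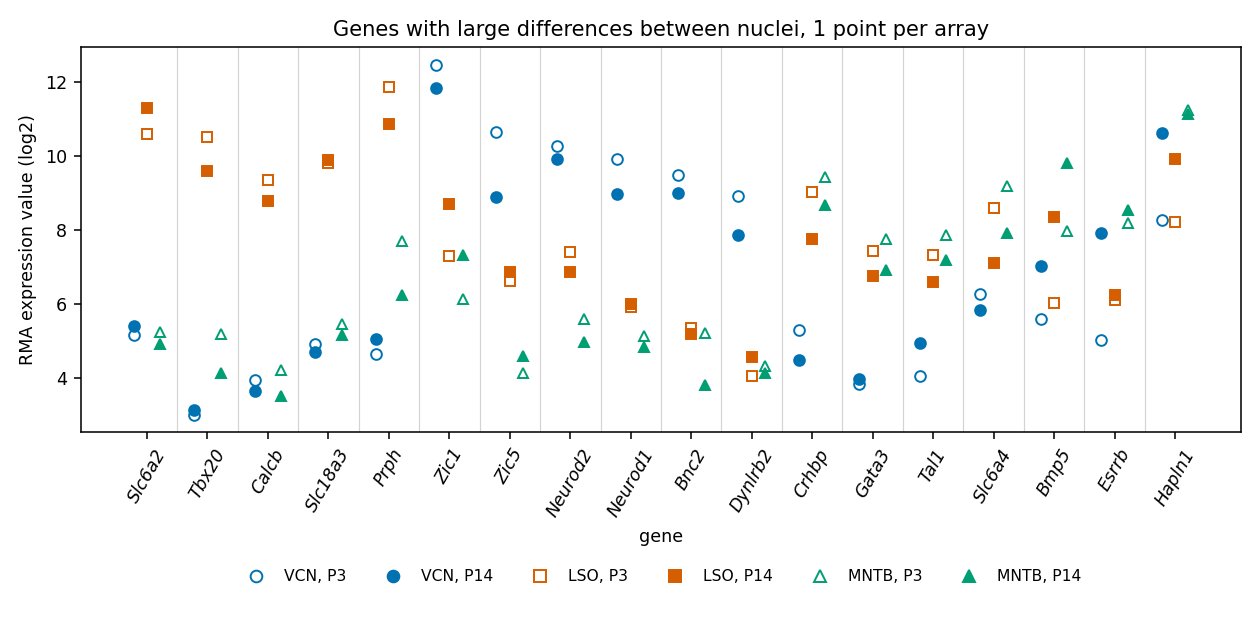
Log2 expression of genes that differed between nuclei, on each array, with P3 as open and P14 as filled markers, VCN as blue circles, LSO as orange squares and MNTB as green triangles. Slc18a3 lies at 9.80 and 9.88 in LSO and between 4.71 and 5.46 on the other 4 arrays.

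In all, 48 genes passed with limma, 22 higher and 26 lower in VCN. The count was 159 and 132 without the VCN arrays of P3 and P14, 4 and 7 without the LSO arrays of P3 and P14, with none of them higher in VCN, and 36 without either MNTB array. Slc6a2, Calcb, Chodl and Slc18a3 passed with every array left out in turn. For the others the highest adjusted p with 1 array left out was reached without the LSO array of P3, at 0.324 for Zic1, 0.127 for Dynlrb2, Bnc2 and Prph, 0.128 for Cbln1, 0.117 for Neurod1, 0.116 for Fam216b, 0.190 for Sema3c and 0.0505 for Tbx20, and without that of P14, at 0.177 for Slc32a1. The 3 probe sets of Prph ranged from -6.50 to -0.47, those of Slc6a2 from -5.66 to -2.33, and the 4 of Slc32a1 from -1.21 to -0.41. With the median of a gene's probe sets Prph was at -1.35 (adjusted p = 0.0928) and Slc32a1 at -0.81 (0.190).

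The granule lineage list was again shifted most, with a median of 2.07, but fry did not call it (adjusted p = 0.223). Of its 9 genes 3, Zic1, Neurod1 and Cbln1, were higher, and 7 adjusted over the list alone. The other 4 lists past camera had adjusted p = 0.852 with an estimated correlation. Myelin genes had a median of 0.40 with none past the test on either count (adjusted p = 0.00219), lost without the LSO array of P3 (0.326) and turned to the other side without the VCN array of P3 (0.361). Astrocyte genes had a median of -0.20 with 2 lower adjusted over the list alone (0.00971), lost without the VCN array of P3 (0.0534) or the LSO array of P14 (0.550). In the glycine and GABA list, with a median of -0.21, Slc32a1 was lower and, adjusted over the list alone, 1 gene was higher and 4 were lower (0.0162). Glutamate receptor genes had a median of -0.14 (0.0429). These last lists did not pass without the VCN array of P14 (0.158 and 0.416) or the LSO array of P14 (0.419 and 0.427). BMP and TGF-beta genes, not independent evidence, had a median of -0.10, with none past the test and 1 higher adjusted over the list alone (list adjusted p = 0.293).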

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

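The tests of dilution as the whole cause, of choroid plexus at P3, of a mislabelled LSO array and of neighbouring motor neurons were chosen only after the results they concern were seen.

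The immature neuron and axon growth list fell by a median of 1.06 log2 units between P3 and P14, while myelin genes rose. To ask whether a growing share of glial RNA was the whole cause, other neuronal genes were compared. The immature neuron median minus that of the potassium channel and presynaptic release members was -0.778 (95% bootstrap interval of the difference -1.61 to -0.119, genes taken as independent). This cannot decide, since those members changed with age themselves. Of 23 potassium channel genes 8 rose and 7 fell, and of 31 presynaptic genes 6 rose and 14 fell. Glial lists moved apart, with medians of 3.09 for myelin and 0.55 for astrocyte genes, which does not bear on the neuronal share. A whole or partial contribution stays open. The median of the 54 potassium channel and presynaptic members was -0.279 with an interval of -0.437 to 0.136, which meets neither bound set beforehand. Maturation of the neurons with age may be a further source and was not tested.

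Motile cilia genes lay higher in VCN than in both other nuclei, starting from Dynlrb2, and 29 measured cilia genes not yet looked at had a median excess of 0.751 at P3 and 0.473 at P14, at percentile 100 of matched random lists at each age, with 26 and 21 of the 29 higher (medians of 0.63 and 0.45, and 23 and 19 higher, with values floored at 4.47). This is consistent with ependymal or other multiciliated cells in the VCN tissue as a candidate source; 14 of the 29 genes were at or above the filter in LSO and MNTB too, and Rsph9 at 8.46 and Dnah11 at 8.26, the members of highest signal in VCN at P3, had an excess of 0.15 and 0.45 at P3 and of -0.37 and -0.12 at P14, against 2.01 and 0.57 for Foxj1 at 8.18. Choroid plexus at P3 is argued against by a median excess of its 6 genes of -0.185 (single genes -0.605 to 0.341), 3 of which LSO and MNTB express too. At P14 it cannot be told apart, because the choroid plexus median was 0.696 and Ttr stood at 12.58 in VCN. A difference between the nuclei themselves stays open and was not tested.

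Cholinergic and motor neuron genes lay higher in LSO at both ages, with a median excess over the higher of VCN and MNTB of 3.85 at P3 and 2.91 at P14 over all 8 measured members. An excess of that size on each array argues against a single mislabelled LSO array. Motor neurons of a neighbouring nucleus in the tissue may be a candidate source and cannot be told apart from neurons of LSO itself: over the 5 members above the filter on at least 1 array the excess changed by a median of 0.01 between the ages (-1.59 to 0.455), and both dissections could hold such cells. Prph stood at 11.86 and Slc18a3 at 9.80 in LSO at P3. The measured excess of those 5 was 2.90 to 5.14 over both ages, that of Ucn was 0.04, and Chat and Mnx1 were not above the unspiked control sets on any array, so that no difference could be seen.

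The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes as for the real split, 5317, were called in 1 of the 10, the real one, and the highest count of the others was 0. The others put the age change into the spread, so their low counts were fixed beforehand. Several of them also did not hold 1 array per nucleus on each side.

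Medians of 6 lists changed in opposite directions between P3 and P14 in different nuclei, 1 array against 1, and the differences were not tested. They were -0.159 in VCN and 1.087 in MNTB for the granule lineage, -0.118 in MNTB and 0.162 in VCN for potassium channels, -0.056 in LSO and 0.23 in MNTB for sodium and HCN channels, -0.158 in MNTB and 0.32 in LSO for glycine and GABA transmission, -0.252 in MNTB and 0.284 in VCN for perineuronal nets, and -0.023 in MNTB and 0.02 in VCN for BMP and TGF-beta signalling. Centring the arrays on their medians took the age median over all arrays from 0.083 to -0.01 for BMP and TGF-beta signalling. For perineuronal nets it went from 0.026 to -0.067. The smaller of these opposite signs may therefore depend on the scaling. Between MNTB and LSO, Endou differed by 2.5 at P3 and -0.496 at P14, and Inhbb by -0.001 at P3 and 2.092 at P14, neither of them tested.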

How the results depend on the processing

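All alternatives were planned except camera with no filter and an estimated correlation together, chosen after seeing the data. Most alternatives could not turn a direction, as filters, thresholds and moderation leave a difference as it is. Testing all probe sets followed the probe set already chosen for a gene. Other single probe sets of Gpr62, Gsn, Rims2, Atoh7 and Pcp2 had the opposite sign for age, that of Pcp2 with a value that rounds to 0. Of the genes past the threshold that the naming rule or the text names, none turned its direction under any alternative. For age, 92 of 116 such genes passed with every array left out in turn, and for MNTB minus LSO, MNTB minus VCN and VCN minus LSO 3 of 9, 5 of 21 and 4 of 14. For age, leaving out either array of a nucleus gives the same difference, so these fits amount to 1 check per nucleus. The median of a gene's probe sets ended 8, 2, 2 and 2 of the calls of such genes, no filter 6, 3, 4 and 1, no intensity trend 6, 3, 5 and 2, and leaving nucleus out of the model 17 for age. Testing all probe sets gave 11135 calls for age and 35, 125 and 75 for these contrasts, as more features were tested. A threshold of 0.10 gave 39, 159 and 113, a minimum of 1 log2 unit 1363 for age, and a filter at the 60th percentile 51 for MNTB minus VCN and 29 for VCN minus LSO. Without the age block 1, 0 and 1 genes passed in limma (165, 262 and 236 at an unadjusted p under 0.05), since the age change then enters the spread. Leaving out 1 array gave 3142 to 4710 calls for age, 4 to 99 for MNTB minus LSO, 17 to 215 for MNTB minus VCN and 4 to 159 for VCN minus LSO, and leaving out both MNTB arrays gave 3138 for age. Leaving out a VCN array kept each difference of MNTB minus LSO and changed only the spread, which that contrast shares with VCN. Other causes were not tested. Other settings kept the counts within 1.5 times. Of 12 list calls for age and 19 for nuclei, 0 and 0 held with an estimated correlation, with or without the filter. That estimate has 2 residual degrees of freedom, and camera with it recovered 0 simulated shifts. Fry called 10 lists for age, of which 8 were among the 12, and 0 for nuclei. Of the 12 it did not call the astrocyte, microglial, presynaptic release and sodium pump and energy supply lists (adjusted p = 0.0653 to 0.128). With 1 array left out, 10 of the 12 age lists passed every time, and 3 of 7, 2 of 7 and 1 of 5 for the nuclei. The myelin list turned its direction between VCN and LSO without the VCN array of P3 (adjusted p 0.361, lowest 2.74e-15 over the arrays left out), and between MNTB and LSO without the LSO array of P3 (0.844) or the MNTB array of P14 (0.889, lowest 0.00012). For these the cause was not tested. Signal over background limits genes near the filter of 5.57, as unspiked control sets lay at 2.84 to 4.42.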

Other observations

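Genes under the filter, tested only when no filter was applied and named after their values were seen, added to the differences between nuclei. All but Th lay within the range of unspiked control sets in the lower nucleus, so bounds with values floored at 4.47 are given. En1, a homeobox gene of the midbrain and hindbrain, was higher in MNTB than in VCN by at least 2.41 log2 units (adjusted p = 0.00878, limma), and its bound in VCN minus LSO was -1.50 (0.0152). For Isl1, a LIM homeobox gene of motor neurons, the bound in VCN minus LSO was -3.53 (0.0456), and for Phox2a, a gene of noradrenergic neurons, -1.78, while Th, another, differed by -1.77 (both 0.0392). For Trhr, the receptor gene of thyrotropin releasing hormone, the bound in MNTB minus LSO was -1.96 (0.0188), and for Neurod6 in MNTB minus VCN -2.80 (0.0255). Enkur, a cilia gene, was higher in VCN than in LSO by at least 2.23 (0.0379).

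A pair of genes stood apart on the VCN array of P14. Gabra6, a GABA receptor gene of granule cells, was at 7.97 there and at 3.26 to 4.37 elsewhere, and Slc17a7, a vesicular glutamate transporter gene, at 8.50 against 3.93 to 4.83. Of the 12 measured members of the granule lineage list 4 were higher on that array than on the VCN array of P3, Gabra6 and Cbln3 (8.54 against 5.27) among them, and 8 were lower, such as Zic4 at 6.73 against 9.37, and the median change of the tested members in VCN was -0.159. These are single values with no test, chosen after they were seen.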
